A study of Mus musculus with 4 samples.

How the data were processed

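Genomic DNA of 4 mouse embryonic stem cell samples (wild type J1, Parp-1 deficient clones 210-58 and 226-47, and J1 treated with PJ34) was extracted with phenol and chloroform, sonicated, and in part immunoprecipitated with an antibody against 5-methylcytidine, per the labels' protocols. Per the labels, the immunoprecipitated DNA carried Cy5 and the whole DNA Cy3, and each sample was hybridised to 1 array with both channels. No dyes were swapped, so any dye effect that depends on the probe is shared by the arrays and cancels only in differences between them. The dose and duration of the PJ34 treatment, the passage of the cells and whether the clones came from separate targeting events are not given in the sources used here.

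Per the file headers, the deposited intensity values came from Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.1. Per the file headers, the processed intensity of each spot is background-subtracted with spatial detrending and dye-normalized around a linear factor per channel (3.44 to 3.69 for Cy3 and 7.61 to 9.82 for Cy5). The deposited value table of the series holds a ratio per spot, which equals the processed Cy5 over Cy3 signal of the same array within 1e-08, is linear and not centred, and has medians of 0.891 for wild type, 0.826 for clone 210-58, 0.848 for clone 226-47 and 0.814 for PJ34. Other deposited columns used were the raw median and background intensity per spot and the flags for outliers, saturation and signal well above background. Median raw signals were 292 to 310 in Cy3 over a background of 42 to 43, and 133 to 154.5 in Cy5 over a background of 56.5 to 57.5, so the IP channel was the weaker one and sets the precision of low log ratios.

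Per array there were 97651 probes and 5950 control spots. Control spots, 442 probes without a position and 30 probes with an outlier flag on any array were left out, and no probe was saturated. Probes were 44 to 60 bases long, mostly 45. The log2 of processed Cy5 over Cy3 was centred on each array's median over all probes other than controls, with no loess or quantile step, since many islands may shift one way. A region was a run of probes on 1 chromosome with neighbouring starts at most 500 bp apart and at least 3 probes, and its value was their mean. This gave 14121 regions with 95657 probes, and the median region was 664 bp long. The genome build of the positions is not given in the sources used here. The gene table at hand was for GRCm38, and only 2.48% of the ends of its protein-coding genes lay within 500 bp of a probe, while 7 chromosomes had probes beyond its last gene, so it was not used to name regions. The 11 gene lists fixed before the data were examined, the genes to be reported in any case, centring on housekeeping islands, the promoter-only setting and the correction for GC content were therefore not run.

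Regions were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on the 2 Parp-1 deficient arrays against the wild type array, with Benjamini-Hochberg adjustment over all regions and a threshold of 0.05. The spread came from the 2 clones alone, with 1 residual degree of freedom, and the fit gave its prior full weight, so each SE follows the general trend with the level of enrichment and hardly reflects how far the clones differed in that region. For this reason values of both clones or their SD are printed for the regions that lead each direction. The p-values measure the spread between these clones and not that between wild type cultures. The test takes the clones as independent, so it cannot separate a lack of Parp-1 from differences they may share through a common ancestor. Arrays without a replicate were compared by a fixed rule of size, a difference of at least 1 on the log2 scale. The same limma fit of the clones against the PJ34 treated array was added after the data had been seen. Regions were named by rules set before the data were examined: the 12 largest rises and 12 largest falls among called regions with both clones moving the same way, the 10 largest gains and losses after PJ34 with at least 75% of probes on the same side, and in each direction the 6 regions with the largest shift shared by all 3 arrays. The further condition that a region has a named gene was dropped. No named region had a group in which every probe's Cy5 signal was not well above background.

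The fit was tested on simulated data for the comparison of the clones with wild type, 20 runs of 14121 regions with the variance between the clones taken in 50 bins of enrichment and 200 regions changed. It recovered 18.4% of changes of 1 and 65.2% of changes of 2 on the log2 scale, all with the right direction, with 20.4 false calls per run (0 to 40), or 19.7% of all calls, above the nominal 5%. The simulated wild type array was given the spread of the clones, so that assumption was not tested. The share of false calls also depends on the 200 regions changed. Regions of a bin were given the same spread, so false calls at regions where the clones vary more than their bin were not tested. Copy number was read from the Cy3 signal of each array minus that of wild type, centred on the median of the autosomal probes, with stretches found by recursive splitting (at least 40 probes and a step of at least 0.2). In simulated data the splitting found 60 of 60 stretches of 100 probes at -0.3, and none in 60 runs without one. The simulated noise was independent between probes, so false stretches from noise shared by neighbouring probes were not tested. The overlap and correlation of differences that share the wild type array were set beside 100 simulated draws of unchanged groups, and the draws for single clones, for the side of PJ34 and for other normalizations were added after the data had been seen. Calls per chromosome were compared with Fisher's exact test, two-sided. Slides were identified from the scanner files. The alternatives covered background correction, normalization, probe filters, the definition of a region, the size of shift, the fit and the arrays in it. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.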

Results

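DNA methylation at CpG islands was profiled in mouse embryonic stem cells of the J1 line, in clones of that line that lack Parp-1, and in J1 cells given the PARP inhibitor PJ34. Parp-1 is a nuclear enzyme that attaches poly(ADP-ribose) to proteins, and PJ34 is a small molecule that blocks this activity. Methylated DNA was pulled down with an antibody against 5-methylcytidine (MeDIP), labelled with Cy5 and hybridised beside Cy3-labelled whole DNA of the same cells to a CpG island array. There were 4 arrays: 1 of wild type J1 cells, 1 of each of 2 Parp-1 deficient clones (210-58 and 226-47), and 1 of PJ34 treated cells. Each array held 97651 probes besides its control spots, and 14121 regions with a median of 6 probes were measured on all 4. A region's value is the mean of the log2 ratio of immunoprecipitated (IP) to whole DNA over its probes after each array was centred on its median, so 0 is the level of a typical probe. The Cy3 signal was well above background for 99.7% of probes on the wild type array, and the Cy5 signal for 94.1%. On clone 210-58, clone 226-47 and the PJ34 treated array the Cy5 share was 93.9%, 98.0% and 91.3%. The small number of arrays limits the precision, and only the Parp-1 deficient group had a replicate. Positions are those in the files, whose genome build is not given in the sources used here, and regions are named by position since the files pair no gene with a probe. For the same reason the Parp1 locus was not examined as a check of the labels.

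The arrays differed in the width of their enrichment profiles. The interquartile range of the region log ratios was 1.37 on wild type, 1.48 on clone 210-58 and 1.39 on PJ34 treated cells, but 0.999 on clone 226-47. With normexp background correction these were 0.775, 0.669, 0.751 and 0.622, so clone 226-47 stood apart less. Highly enriched regions, those at 2 or above, made up 9.94% of regions in wild type, 8.67% in clone 210-58, 6.31% in clone 226-47 and 9.79% after PJ34. Among regions whose mean over the 4 arrays lay between 2 and 3, the median difference from wild type was -0.72 in clone 226-47, -0.26 in clone 210-58 and 0.00045 under PJ34. Among those above 3 it was -0.40, 0.03 and 0.47, so only clone 226-47 was lower in both. Among those below -1 it was 0.43 in clone 226-47 and -0.16 in clone 210-58. Pearson correlations across regions, which are not independent replicates, ran from 0.916 between wild type and clone 210-58 to 0.960 between the 2 clones. Clone 226-47 and PJ34 treated cells, which shared a slide, were nearly as close, at 0.958.

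The first comparison asks which CpG islands gained or lost methylation in cells without Parp-1. The clearest differences were falls at 6 regions that were strongly enriched in wild type cells, at 2.89 to 3.82, and lay between -1.98 and 0.11 in both clones. The region with the largest fall lay on chromosome 7 from 6333486 to 6334587 (9 probes), where wild type cells had 3.49, clone 210-58 had -1.60 and clone 226-47 had -1.13, a difference of -4.85 (SE 0.29, limma adjusted p = 6.56e-57). On chromosome 11 from 22872000 to 22873052 the clones differed from wild type by -4.46 (SE 0.29, limma adjusted p = 1.12e-47). The regions on chromosome 17 from 12584752 to 12585952 and on chromosome 11 from 11925467 to 11926345, with 10 probes each, differed by -3.90 (SE 0.32) and -3.65 (SE 0.33). A pair of neighbouring regions on chromosome 2, from 173940167 to 173940489 and from 173941465 to 173943988, differed by -3.87 (SE 0.34) and -3.64 (SE 0.33). In these 6 regions the clones were within an SD of 0.58 of each other, and PJ34 treated cells lay above wild type by 0.36 to 1.003, against a median of 0.27 at the other 1045 regions at 2.5 or more in wild type. That set was not matched for level, and regions whose mean over the 4 arrays was above 3 had a median of 0.47. The group of 6 was chosen after its values were seen. No region showed the opposite, from below 0.5 in wild type to 2.5 or more in both clones.

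**Figure D1:**
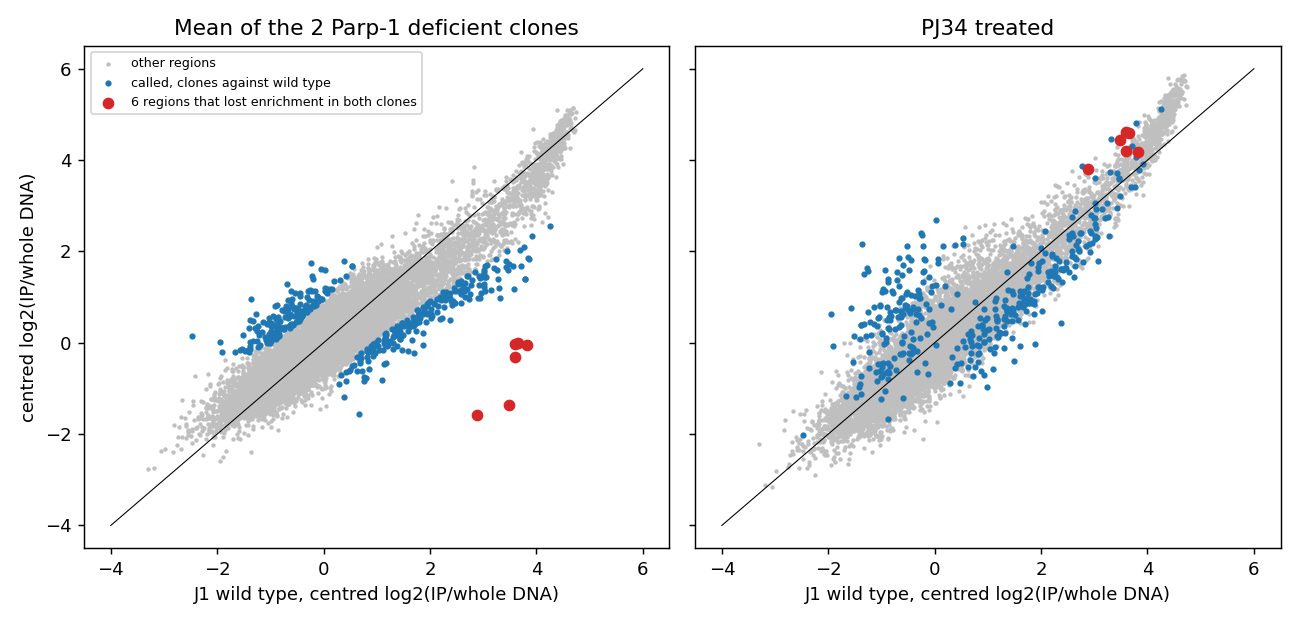
Centred log2 ratio of IP to whole DNA of the 14121 regions in wild type cells (x axis) against the mean of the 2 Parp-1 deficient clones (left) and the PJ34 treated array (right), with the line of equal values. Blue points are regions called in the clones against wild type, and red points are the 6 regions at 2.89 to 3.82 in wild type that lay at 0.11 or below in both clones and above the line after PJ34.

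In all, 393 of 14121 regions (2.78%) passed limma's test of the 2 clones against wild type with Benjamini-Hochberg adjustment at 0.05, and 390 of them moved the same way in both clones, 168 up and 222 down. Falls of 2 or more on the log2 scale were seen in 13 of these regions and rises of 2 or more in 2. By the mean of the 4 arrays, 100 of the 168 called rises and 91 of the 225 called falls lay between 0 and 1, and 0 rises and 39 falls between 2 and 3. The other 6 of the 12 largest falls kept part of their enrichment or started low. The regions on chromosome 8 from 125661363 to 125662022, on chromosome 7 from 128479186 to 128479782 and on chromosome 13 from 56531867 to 56532553 differed by -2.40 (SE 0.39), -2.39 (SE 0.41) and -2.38 (SE 0.41), from 3.57, 3.79 and 3.79 in wild type. On chromosome 9 from 91181853 to 91182451 and on chromosome 17 from 87042133 to 87043537 the differences were -2.10 (SE 0.38) and -2.04 (SE 0.45). The region on chromosome 19 from 31148579 to 31149216 was at 0.66 in wild type, -1.87 in clone 210-58 and -1.26 in clone 226-47, where 2 and 3 of its 5 probes had Cy5 well above background.

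The 12 largest rises ran from 1.72 to 2.61, with adjusted p-values from limma of 6.05e-05 or less, and every one of them was higher in clone 210-58 than in clone 226-47. No rise was called after quantile normalization (27 calls, 0 rises) or after intensity loess (0 calls). The largest, on chromosome 2 from 33402658 to 33402988 (4 probes), was at -2.47 in wild type, 1.10 in clone 210-58 and -0.81 in clone 226-47, so the clones differed from each other (SD 1.35) by more than the fit's SE of 0.40 shows. Only 2 of its 4 probes had Cy5 well above background in wild type, so the size of its rise is uncertain, and on chromosome 4 from 99145322 these were 4 of 7. On chromosome 12 from 81087296 they were 2 of 3, with an SD over probes of 1.75 in wild type. The regions on chromosome 10 from 79798479 to 79798816 and from 80547194 to 80548214 rose by 2.33 (SE 0.29) and 1.99 (SE 0.33), with SDs between the clones of 1.20 and 1.13. The rise was 1.97 (SE 0.30) on chromosome 12 from 81087296 to 81087582 and 1.97 (SE 0.38) on chromosome 4 from 99145322 to 99146048. On chromosome 15 from 79760709 to 79760925 and chromosome 3 from 93528964 to 93531113 it was 1.90 in both cases (SE 0.29 and 0.30). The other 5 lay on chromosome 7 from 30174206 to 30174511 (1.81) and from 49503392 to 49503677 (1.75), on chromosome 16 from 35960923 to 35961453 (1.73), on chromosome 5 from 125679132 to 125680175 (1.73) and on chromosome 11 from 100529893 to 100530474 (1.72). Over the 12 the SD between the clones ran from 0.55 to 1.35, above the SEs of 0.29 to 0.40. Over all called rises the median difference from wild type was 1.53 in clone 210-58 and 0.88 in clone 226-47, whereas over called falls it was -1.35 and -1.30. PJ34 treated cells were above wild type in all 12 of the largest rises. They were above it in 160 of the 168 called rises (median 1.24, clone mean 1.20). On their shared slide, clone 226-47 was above PJ34 treated cells in 61 of the 168. Of all regions higher by at least 1 in the clones, PJ34 treated cells were above wild type in 95.8%. Simulated unchanged groups with a shared control gave 88.7% to 96.9%. The side of PJ34 therefore does not show whether the rises were shared or particular to the clones. A low value of the single wild type array cannot be told apart from a shared change.

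**Figure D2:**
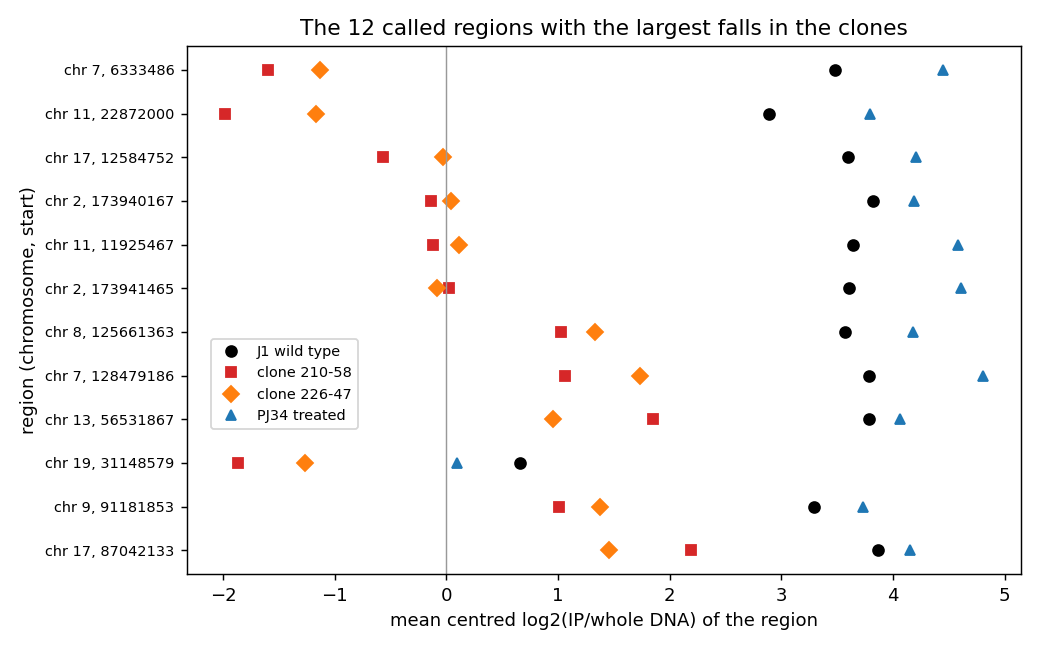
Mean centred log2 ratio of IP to whole DNA (x axis) on each of the 4 arrays for the 12 called regions with the largest falls in the Parp-1 deficient clones (y axis, chromosome and start). Each symbol is 1 array, and in the top 6 rows both clones lie between -1.98 and 0.11 while wild type and PJ34 treated cells lie at 2.89 or above.

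By size alone, 520 regions differed from wild type by at least 1 on the log2 scale in the mean of the clones with both clones on the same side, 191 higher and 329 lower. Clone 210-58 alone had 891 such regions (467 higher, 424 lower) and clone 226-47 alone 554 (136 higher, 418 lower). Wild type and clone 210-58 shared a slide, as did clone 226-47 and the PJ34 treated array, so the count of 891 is also the within-slide value, and with slide as a block no residual degree of freedom was left for a test. The other slide held no wild type array. The count of calls was 182 in limma without the mean-variance trend, 27 after quantile normalization and 0 after intensity loess, and normexp background correction turned the balance to 322 rises and 104 falls. The normexp setting also started from raw median signals in place of the processed ones. The test had 1 residual degree of freedom, assumed that the single wild type array varied like the clones, and in simulated data made 19.7% false calls among all calls. The simulation made the same assumption, so it does not show the error if wild type cultures vary more than the clones. It also gave regions of like enrichment the same spread. In the data the median SD between the clones was 0.32 over called regions and 0.21 over all, so the share of false calls may be higher.

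The second comparison asks which islands differed in J1 cells given the inhibitor, and it has 1 array on each side, so no p-value is given and its values have no replicate check. At least 1 on the log2 scale separated 522 regions, 345 higher and 177 lower after PJ34. The balance depended on the processing: a size of 0.5 gave 1563 higher and 1633 lower, and medians over probes 437 and 403. The largest differences were gains. On chromosome 10 from 79798479 to 79798816 the value was -1.37 in wild type and 2.17 after PJ34, a difference of 3.54. Regions on chromosome 15 from 79760709 to 79760925, chromosome 7 from 30174206 to 30174511 and chromosome 5 from 135230677 to 135230937, each of 3 probes, were higher by 2.91, 2.84 and 2.83. The next 3 lay on chromosome 3 from 88418822 to 88419272 (2.68), chromosome 19 from 6413082 to 6413399 (2.66) and chromosome 7 from 101694600 to 101694862 (2.66). The last 3 of the 10 largest gains were on chromosome 10 from 80547194 to 80548214 (2.60), chromosome 4 from 99145322 to 99146048 (2.59) and chromosome 14 from 43910846 to 43911604 (2.54).

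The 10 largest losses after PJ34 ran from -1.95 to -1.64. The largest was on chromosome 1 from 152755387 to 152755883, from 0.97 in wild type to -0.98 after PJ34. Regions on chromosome 19 from 47918611 to 47919310 and chromosome 8 from 61804522 to 61805239 went from 2.38 and 1.88 to 0.43 and -0.02. The others lay on chromosome 13 from 12574643 to 12575041 (-1.89), chromosome 4 from 129610050 to 129610331 (-1.89), chromosome 17 from 15100959 to 15101181 (-1.78), chromosome 8 from 47473889 to 47474475 (-1.70), chromosome 6 from 17980189 to 17980692 (-1.68), chromosome 4 from 48145833 to 48146539 (-1.67) and chromosome 5 from 53337432 to 53337740 (-1.64). No region at 2.5 or more in wild type was below 0.5 after PJ34. The 2 arrays lay on different slides, so slide and treatment cannot be told apart here, and normexp background correction left 94 gains and 5 losses. The size of some losses is uncertain: under PJ34 Cy5 was well above background for only 1 of 3 probes in the regions on chromosome 4 from 129610050 and chromosome 17 from 15100959, and for 3 of 5 in that on chromosome 1.

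Whether the clones and PJ34 treated cells changed at the same islands was read from differences that share the single wild type array. In both, 113 regions were higher by at least 1 and 47 were lower. Simulated groups with no change, set against a shared control, gave 50.6 regions higher (33 to 67 in 100 draws) and 51.5 lower (36 to 74), and independent lists of these lengths would share 4.67 and 4.12. With clone 210-58 alone 214 regions were higher in both (34 to 79 simulated), and with clone 226-47 alone 48 (40 to 76). Without further normalization the excess of shared rises was thus seen with clone 210-58 and not with clone 226-47. Clone 226-47 had the narrower profile, and single clones were not compared with simulations after other normalizations. Shared falls were 58 with clone 210-58 alone (44 to 84) and 33 with clone 226-47 alone (41 to 83), the latter below the simulation. Shared rises numbered 20 with normexp (2 to 14 simulated) and 11 with intensity loess (0 to 4), and shared falls 3 (1 to 12) and 2 (0 to 4). After quantile normalization shared falls exceeded the simulation too, at 57 (3 to 17), so the balance of rises and falls depends on the processing. Correlations with the PJ34 difference were 0.569 for clone 210-58, above the 0.485 to 0.522 of the simulation, and 0.421 for clone 226-47, below its 0.483 to 0.519. For the mean of the clones the correlation across regions was 0.554, below the simulated 0.578 (0.563 to 0.598). The covariance was 0.116, above the simulated 0.0997 (0.0960 to 0.105). The wild type group could not be split, so part of any excess may come from its array. A slide effect, which clone 226-47 and PJ34 treated cells could share, was not part of the simulation. The regions highest above wild type in all 3 other arrays were those on chromosome 4 from 99145322 to 99146048 (at least 1.53 in each), chromosome 10 from 79798479 to 79798816 (1.48), chromosome 7 from 30174206 to 30174511 (1.30), chromosome 15 from 79760709 to 79760925 (1.29), chromosome 11 from 69376370 to 69376566 (1.28) and chromosome 7 from 49503392 to 49503677 (1.27). The regions furthest below wild type in all 3 lay on chromosome 4 from 48145833 to 48146539 (-1.67 or lower in each), chromosome 19 from 47918611 to 47919310 (-1.61), chromosome 8 from 61804522 to 61805239 (-1.58), chromosome 9 from 63725523 to 63725912 (-1.33), chromosome 6 from 90290445 to 90290911 (-1.32) and chromosome 1 from 4486985 to 4487793 (-1.30). Tested directly with limma, the clones differed from PJ34 treated cells at 190 regions, higher in the clones at 133 and lower at 57. Without the mean-variance trend 95 regions differed, after quantile normalization 10 and after intensity loess 1, and after either normalization every one was lower in the clones.

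The clones also differed from each other. At least 1 on the log2 scale separated them at 337 regions, 199 higher in clone 210-58 and 138 higher in clone 226-47. Which clone was higher more often depended on the processing: scaling by the median absolute deviation gave 54 and 238, intensity loess 21 and 36, and a size of 0.5 gave 1424 and 2010, while quantile normalization gave 97 and 23. The median SD between the clones was 0.21 over all regions and 0.32 over called regions.

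The whole DNA channel showed that the cells did not carry the same chromosomes. Relative to wild type, the median Cy3 signal of chromosome 8 was -0.44 in clone 210-58 and -0.46 in clone 226-47 on the log2 scale, with 96.7% and 97.7% of its probes below 0, and -0.02 in PJ34 treated cells. Chromosome 11 was at 0.50 in clone 210-58, with 98.2% of its probes above 0, and at 0.04 in clone 226-47, and the former was 0.31 with normexp background correction. The end of chromosome 14, from 92774172 to 122762203, was at -0.77 in clone 210-58 and -0.76 in clone 226-47. The border was the same in both at the resolution of the search, which did not try a border at every probe. The clones may thus share an ancestor, which was not tested. The limma test takes them as independent, so differences from such an ancestor would also be called. Clone 210-58 had a stretch at -0.44 on chromosome 6 from 67464970 to 89328027, where clone 226-47 was at -0.09, with 74.6% of its probes below 0, and PJ34 treated cells were at -0.02. Within chromosome 11 a short stretch from 100971981 to 101800510 was at 1.22 in clone 210-58 and at 0.02 in clone 226-47. Clone 226-47 had a stretch at -0.79 on chromosome 12 from 106263981 to 111039302, where clone 210-58 was at -0.04. A short stretch of chromosome 2 lay at -0.29 in clone 210-58 (164188904 to 164689063) and at -0.28 in clone 226-47 (164460818 to 164803724), and in PJ34 treated cells these were at -0.14 and -0.13. Chromosome X was at 0.19 in clone 210-58, 0.08 in clone 226-47 and 0.07 in PJ34 treated cells. On the 15 chromosomes other than 6, 8, 11, 14 and X, medians lay between -0.02 and 0.04 on all 3 arrays. The difference from wild type does not show which of the lines has the usual copy number. Of the 2643 regions in chromosomes or stretches that differed by at least 0.15 in a clone, 64 were called (2.42%), against 329 of 11478 elsewhere (2.87%). On chromosome 8, 20 of 810 regions were called as rises, or 2.47% against 1.11% elsewhere, which did not pass Fisher's exact test over 40 such tests (adjusted p = 0.0824).

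**Figure D3:**
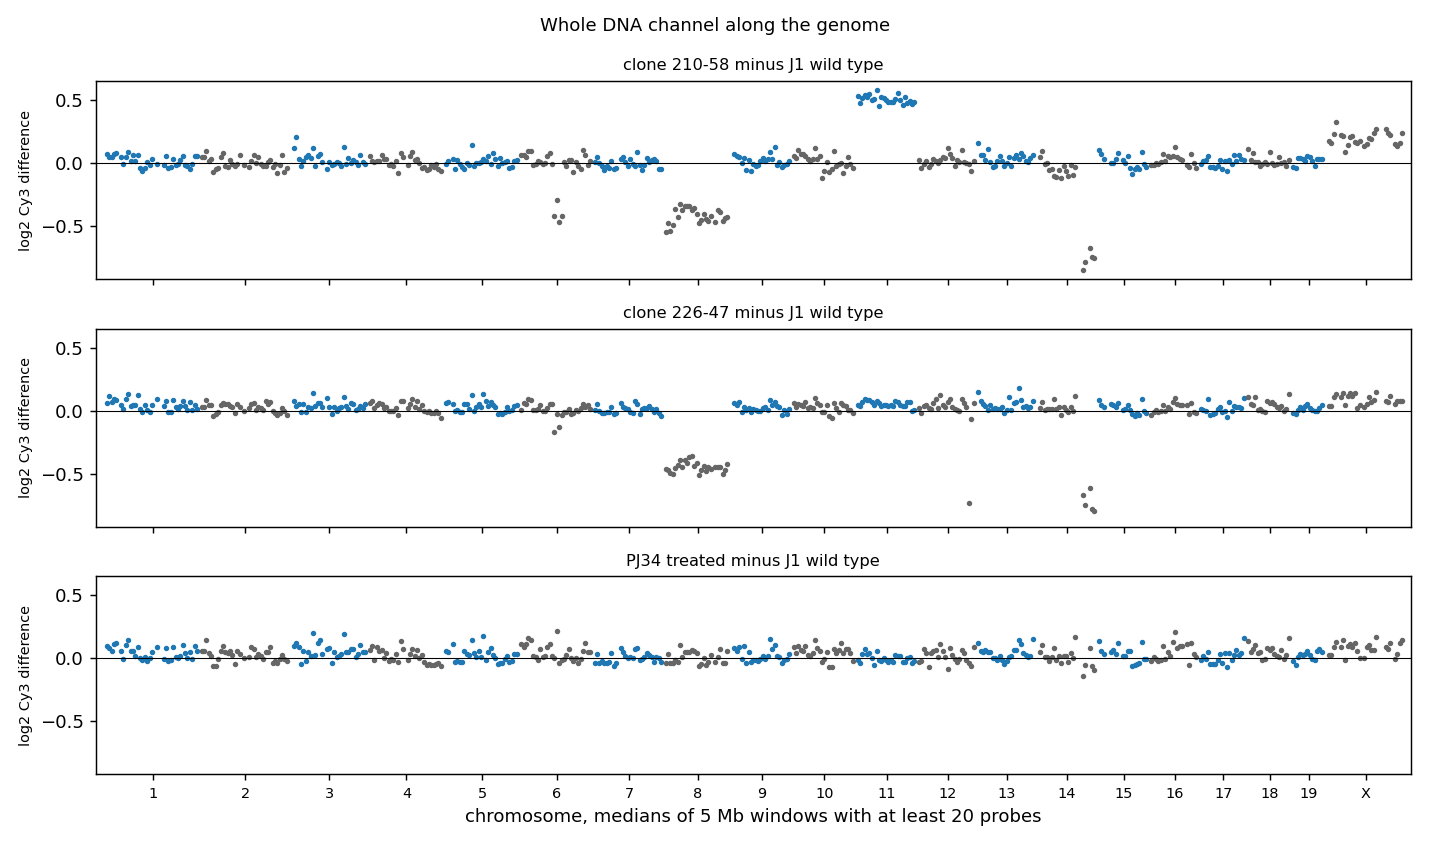
Log2 Cy3 signal of whole DNA minus that of wild type (y axis) along the chromosomes (x axis, points are medians of 5 Mb windows with at least 20 probes) for both Parp-1 deficient clones and PJ34 treated cells. Chromosome 8 and the end of chromosome 14 lie below 0 in both clones, chromosome 11 lies near 0.50 in clone 210-58, and PJ34 treated cells stay near 0.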

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

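The test of the clones against PJ34 treated cells, and the tests of explanations in this part, were chosen after the values had been seen. Of the regions named in the report, 15 differed between the clones and PJ34 treated cells in limma's test of that difference, which compares 2 arrays with 1. In 11 of them the clones lay below wild type and PJ34 treated cells above it. All 11 were at 2.5 or more in wild type, where PJ34 treated cells lay above wild type in general (median 0.27 at the 1045 such regions without a complete loss), so that side alone does not set them apart. Of all regions lower by at least 1 in the clones, PJ34 treated cells were below wild type in 86.0% (88.1% to 97.6% in simulated unchanged groups with a shared control), and of those higher by at least 1 they were above it in 95.8% (88.7% to 96.9%). The 11 included the 6 regions that lost their whole enrichment, where the clones minus PJ34 difference was -5.81 (chromosome 7 from 6333486), -5.37 (chromosome 11 from 22872000), -4.64 (chromosome 2 from 173941465), -4.59 (chromosome 11 from 11925467), -4.51 (chromosome 17 from 12584752) and -4.23 (chromosome 2 from 173940167). The other 5 of the 11 were at -3.41 (chromosome 7 from 128479186), -3.01 (chromosome 8 from 125661363), -2.65 (chromosome 13 from 56531867), -2.53 (chromosome 9 from 91181853) and -2.33 (chromosome 17 from 87042133). In 3 regions both stood above wild type, with a difference of -1.31 on chromosome 5 from 135230677, 1.24 on chromosome 3 from 93528964 and 2.16 on chromosome 2 from 33402658. On chromosome 8 from 47473889 the clones minus PJ34 difference was 1.56, but the clones, at 1.06 (210-58) and -0.29 (226-47, SD 0.95), lay on opposite sides of the 0.53 of wild type. Without the mean-variance trend 13 of the 15 passed the threshold, the exceptions being chromosome 5 from 135230677 (adjusted p = 0.0794) and chromosome 3 from 93528964 (adjusted p = 0.122). After quantile normalization 8 of the 15 passed and after intensity loess 1, none of them among the 3 that were higher in the clones than under PJ34.

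The loss of enrichment at 6 regions in both clones was set against 3 explanations. Loss of the DNA itself is argued against by the Cy3 signal, which at these regions lay 0.0703 above the chromosome's median difference from wild type (range 0.00 to 0.41). Weaker immunoprecipitation on the clone arrays is argued against as the whole cause, since the other 1045 regions at 2.5 or more in wild type differed by a median of -0.37 and by no more than -2.40, against -3.64 or lower at the 6. The falls were seen within slide 1 (clone 210-58 minus wild type, -3.58 to -5.09), and within slide 2 clone 226-47 differed from PJ34 treated cells by -4.14 to -5.57, against a median of -0.82 and a lowest value of -3.39 at the other 1045. The 6 were set apart by their low values in the clones, so the lowest values of the others follow in part from that choice. A lack of PARP activity stays open. PJ34 treated cells lay above wild type at the 6 regions by a median of 0.92, against 0.27 at the other 1045. Regions whose mean over the 4 arrays was above 3 had a median of 0.47. The exposure is not given in the labels, however, and 1 array was run. The loss may as well have arisen while the clones were derived or in a shared ancestor of them, which no array of an unmodified subclone tests here.

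The log ratios of chromosomes 8 and 11 were shifted against their Cy3 differences. Copy number of these chromosomes is consistent with this: among regions with a mean log ratio of 0 or less, chromosome 11 lay at -0.20 relative to other autosomes in clone 210-58 (95% bootstrap interval over regions -0.23 to -0.15) and at -0.00011 in clone 226-47, whereas chromosome 8 lay at 0.19 in clone 210-58 and 0.18 in clone 226-47. Lower methylation along chromosome 11 in clone 210-58 is argued against by its regions above 1.5, at 0.065 (-0.06 to 0.17). After centring per chromosome, chromosome 8 held 8 called rises in place of 20 but 29 called falls in place of 11, and chromosome 11 held 19 rises in place of 9 and 10 falls as before. It stays open whether the clones lost a copy of chromosome 8 or the J1 culture had gained one.

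Wild type stood apart from all 3 other arrays by at least 0.75 the same way at 263 regions, lower at 115 of them. A defect confined to part of the wild type array is argued against as the cause of shifts of whole regions. Probes of these regions lay a median of 178.1 spots apart, within the 172.2 to 186.2 of random probes. In clone 210-58 a median of 100% of a region's probes shifted the same way. Whether shifted probes of different regions lay close together on the array was not tested. A chance value of the single wild type array cannot be told apart from a change shared by the clones and PJ34 treated cells. The covariance of their differences exceeded the simulated one by 0.0165 while their correlation was below it, and the spread of wild type cultures was not measured. With only 3 ways to choose the lone array among wild type and the clones, no share under 0.05 can be had. More regions were called with wild type as the lone array than with either clone. With the PJ34 treated array added to the choice, wild type as the lone array again gave the most calls. A wild type array that stands apart for any reason would give this too.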

How the results depend on the processing

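Centring per chromosome, leaving out chromosomes 6, 8, 11, 14 and X, and the test against PJ34 were added after the data had been seen, and the cause of the changes below was not tested unless named. The 6 regions that lost their enrichment fell in every setting that measured them (5 of them with at least 5 probes, 4 without the 5 chromosomes), by between -2.09 (PJ34 array added to the clones) and -6.04, and passed limma's threshold wherever tested except after intensity loess (adjusted p = 0.0702 to 0.317). Calls in the clones numbered 0 after loess (1891 at an unadjusted p under 0.05, against 1693), where the prior had 4.14 degrees of freedom, and 27, all falls, after quantile normalization (2720 unadjusted). They numbered 781 with scaling by the median absolute deviation (397 rises), which shared 384 of the 393 calls, 182 without the trend (64 rises), 249 with the PJ34 array added to the clones (150 rises), and 3006 of 97179 single probes. Normexp background correction, run on median signals, gave 426 calls, of which 216 were shared, and moved the median difference of all regions to 0.11. Calls against PJ34 numbered 1 after loess (1193 unadjusted), 10 after quantile normalization and 297 with a gap of 200 bp. Shifted regions of the clones numbered 156 with normexp, 100 with loess, 259 with at least 5 probes, and 3209 and 95 at sizes of 0.5 and 1.5. For PJ34 these were 99, 65, 307, 3196 and 90, with 840 for medians over probes. For the shared regions they were 23, 13, 85, 1353 and 25. For the difference between the clones they were 95, 57, 172, 3434 and 39, with 120 after quantile normalization and 559 for medians over probes. Leaving out 1 clone gave 554 to 891 shifted regions and 81 to 272 shared ones, the higher counts with clone 210-58 alone, and -0.46 to -0.44 for chromosome 8 in the Cy3 channel. Without 1 clone no residual degree of freedom is left, so the calls have no value there. The interquartile range was 0.775 on wild type, 0.669 on clone 210-58, 0.622 on clone 226-47 and 0.751 on PJ34 with normexp, and 1.02, 0.933, 0.763 and 0.931 with loess. It was 1.25 on clone 226-47 with quantile normalization and with scaling, and 1.18 on PJ34 with at least 5 probes. With normexp the Cy3 difference was -0.49 for chromosome 8 and 0.31 for chromosome 11. Of 510 pairs of a region named for the clones or for all 3 arrays and a setting, 423 kept their call or their value within the spread, 51 lost the call, nearly all with loess or quantile normalization, 36 moved and none turned sign, and of 264 pairs for PJ34 45 moved and none turned sign. No paired analysis was possible because only the Parp-1 deficient group has more than 1 array. Slide as a block, housekeeping centring, GC correction and promoter-only lists were not run, and leaving out saturated probes removed none. The weak Cy5 signal limits low log ratios.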

Other observations

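The 442 probes without a position were enriched in every sample, with a median centred log2 ratio of 1.31 in wild type, 1.47 in clone 210-58, 1.31 in clone 226-47 and 1.43 after PJ34.

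Under PJ34 no stretch of the whole DNA channel passed the rule, and of the short stretches found in the clones only those on chromosome 2 were below -0.1 there, at -0.14 and -0.13. The stretch at 1.22 on chromosome 11 of clone 210-58, from 100971981 to 101800510, held 110 probes and came on top of the chromosome's 0.50.

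A hypothesis formed and tested after the calls were seen was that islands close together changed together in the clones. Among adjacent regions at most 50000 bp apart, 13 pairs were called in the same direction and 0 in opposite directions, against means of 2.95 and 2.51 when calls were permuted within 10 levels of enrichment (p = 0.0001, the smallest that 10000 permutations can give). Regions under 2000 bp apart may share DNA fragments, and without those 7 pairs were left against a mean of 2.5 (permutation p = 0.02). One of the pairs joined the region on chromosome 7 from 6333486, which lost its whole enrichment, to a region from 6300350 that differed by -1.71.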
